A study of Vitis rotundifolia with 18 samples.

How the data were processed

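RNA from berries of the muscadine grape, Vitis rotundifolia, was sequenced in 18 libraries that form 6 groups of 3. The groups are the cultivars Noble and Carlos at 3 stages of the E-L scale, a numbered scale of grapevine growth: E-L 32 (bunch closure), E-L 35 (veraison, the onset of ripening) and E-L 38 (maturity). Per the labels' protocols, total RNA was extracted with TRIZOL, treated with DNase and made into libraries with a directional kit, which keeps the strand of the RNA. Cultivar, stage and replicate number were taken from the labels. Nothing in the labels says that replicates came from separate vines or harvests, so the p-values measure only the spread between these samples, which may be technical.

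The authors deposited 1 table of gene-level estimates per library, with 27228 identifiers in the same order in every library. Per the submitters' processing notes, STAR 2.7.6a and RSEM 1.3.3 were used. The genome build, the annotation and whether strand entered the counting are not given in the sources used here. Per the file headers, each table holds an expected count, TPM and FPKM for every identifier. The deposited expected counts are estimates that share a read among the genes it matches, so some are not whole numbers. The TPM values deposited by the authors are relative transcript abundances, scaled by length and to a common total per library. The FPKM values deposited by the authors are fragment counts scaled by gene length and library total. TPM and FPKM were not tested here. Expected counts were rounded to whole numbers for all tests. In at least 1 library 2667 genes had expected counts that were not whole, and values of such genes depend on how reads were divided among similar genes.

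Of the identifiers, 26588 begin with VIT_ and 640 with ENSRNA. The ENSRNA identifiers held at most 697 expected counts in any library. The files do not pair the identifiers with gene names. A reference table of 27334 genes of the Carlos assembly VITMroCarlos_v1.3 was searched for them and 0 identifiers matched. The 20 gene lists planned for berry ripening (pigment, sugar, acid, cell wall, hormone and stress pathways among them) could therefore not be tested with this table, and 0 of them were matched. No other reference was searched. The species of the reference that carries these identifiers was not established here. Whether reads of both cultivars match that reference equally well is not known. Genes are named by identifier only, and no function is given for any of them.

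Genes with too few counts were removed with the filterByExpr function of edgeR, which left 17657 genes. Library sizes were scaled by TMM. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, fitted to all 18 libraries with 1 coefficient per group. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values are rounded expected counts scaled to a common library total after TMM. Comparisons were made between successive stages within a cultivar, between cultivars at each stage, and for the difference between cultivars of each stage step (the interaction). Stage steps averaged over both cultivar labels were added after the data were examined, because they do not depend on which library of a stage carries which cultivar name. Overlaps of calls were set beside the number that independent lists of the same sizes give. The comparisons set side by side in this way shared no library.

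Named genes followed a rule fixed before the data were examined. In each comparison they are the 2 called genes with the highest and the 2 with the lowest fold change, among genes with a mean of at least 10 CPM in some group compared. For comparisons of 2 groups, libraries of the groups also had to show no overlap. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 counts over the group's libraries. Where a group held 1 to 3 counts, the ratio is the mean CPM of the higher group over the pooled CPM of the lower group (its counts over its summed scaled library sizes), with the exact Poisson 95% interval of that count. Floors and intervals cover counting error only. Leaving out 1 library of a group at or near 0 also lowers the pooled depth behind its bound or ratio, and each of the 9 named bounds moved by over 1.5 times for some library left out. Principal components were computed from log2 CPM (prior count 2) of the 500 most variable genes.

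Totals ranged from 18919160 to 30843026 expected counts per library. Counts were simulated from each gene's mean over all 18 libraries, with the real spreads and library sizes. Every group had the same mean except for the genes changed in 1 group. Of these, 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. The edgeR test of Noble E-L 35 against E-L 32 then ran on 17215 genes. It recovered 14.9% of genes changed 1.5-fold, 46.3% of those changed 2-fold and 74.2% of those changed 4-fold. Of 95 simulated calls, 5 were false. The simulated interaction from E-L 35 to E-L 38 ran on 17223 genes and recovered 2.99%, 19.4% and 66.7% of genes changed by those folds, with 1 false call of 60. The real comparisons called far more genes, which makes the adjustment of p-values less strict. These shares therefore do not carry over to the real tests.

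Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter beyond a count above 0, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit to the libraries of the groups compared only, the replicate number as a block, each replicate left out in turn, and a call that also requires a 2-fold change. Leaving out together 3 libraries that stood apart from their replicates, and exchanging the cultivar labels at E-L 38, were chosen after the data were examined.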

Results

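Berries of 2 muscadine cultivars, the dark-skinned Noble and the bronze-skinned Carlos, were profiled by RNA sequencing at bunch closure (E-L 32), veraison (E-L 35) and maturity (E-L 38). The stated purpose was to find genes that change as berries ripen, in both cultivars or in 1 of them. Each of the 6 groups held 3 libraries. Noble libraries held 18919160 to 24406869 expected counts at E-L 32, 22554635 to 30719459 at E-L 35 and 21767325 to 26109619 at E-L 38. Carlos libraries held 22438017 to 30843026, 24043973 to 26957653 and 23821536 to 26855807 at the same stages. A group's floor of 3 counts lay between 0.0361 and 0.0444 CPM.

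Fewer genes gave any count as ripening went on. Libraries of Noble had counts for 19087 ± 80.9 genes (SD, n = 3) at E-L 32, 18322 ± 477 at E-L 35 and 17697 ± 158 at E-L 38. Those of Carlos had counts for 18639 ± 131, 18215 ± 240 and 17618 ± 201 genes. At E-L 32 the 10 most abundant genes took 3.90% to 3.98% of the counts in Noble and 4.71% to 5.01% in Carlos. At E-L 35 they took 5.03% to 11.2% in Noble and 5.76% to 29.6% in Carlos. At E-L 38 they took 5.74% to 6.34% in libraries labelled Noble and 5.64% to 6.55% in those labelled Carlos. Depth differed between libraries, and the numbers of detected genes were not scaled for it or tested.

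Libraries of E-L 32 lay apart from those of both later stages on the first principal component. This component held 75.6% of the variance of the 500 most variable genes (61.3% with all tested genes), and the second held 10.7%. The share of variance due to stage was not computed. On the first component Noble E-L 32 replicate 1 lay at -52.5, against -79.1 and -82.9 for replicates 2 and 3. Carlos E-L 35 replicate 3 lay at 3.90, against 46.6 and 46.4 for replicates 1 and 2. In that Carlos library the identifier VIT_07s0005g03420, singled out after its values were seen, took 9.56% of all counts and stood at 114697 CPM, against 5364 and 5130 CPM in the other replicates. The same gene stood at 24406 CPM in Noble E-L 35 replicate 2, against 4697 and 5604 CPM in replicates 1 and 3. These 3 libraries, chosen after the data were examined, are called atypical here. Carlos E-L 38 replicate 3 also stood apart by the correlation of log2 CPM with its replicates, at r = 0.976 and 0.977, where Noble E-L 32 replicate 1 had 0.979 and 0.976. Its chi-square per degree of freedom was 91.6 and 83.1, against 22.4 and 25.7 for that Noble library. It was left out only by itself, which gave 5859 genes for Carlos E-L 38 against E-L 35 (7149 with it) and 3454 between the labels at E-L 38 (4130 with it). Pearson correlations of log2 CPM across genes between replicates ran from 0.920 to 0.994, and no pair of replicates differed by as little as sampling noise (chi-square per degree of freedom of at least 2.96).

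**Figure D1:**
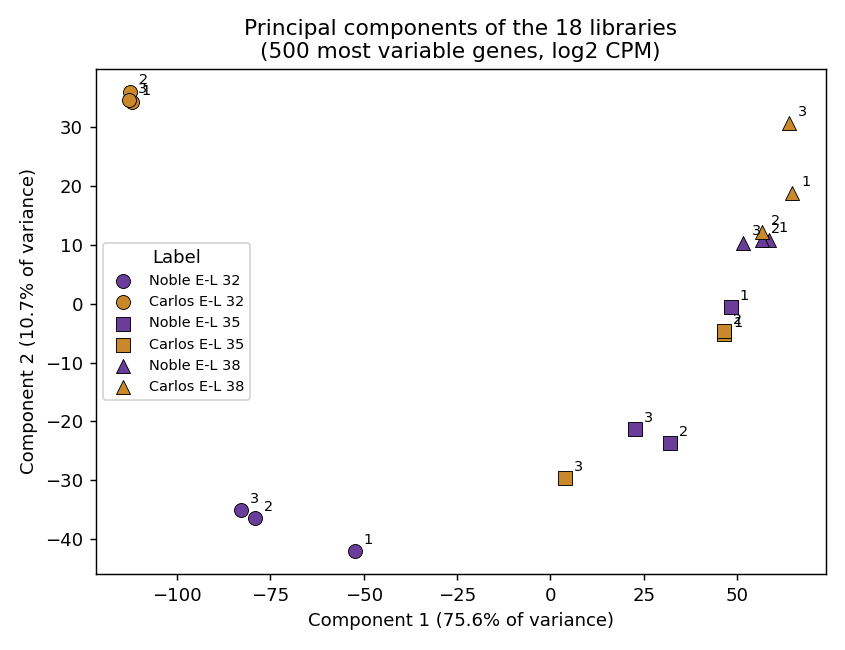
Principal components 1 (75.6% of variance, horizontal axis) and 2 (10.7%, vertical axis) of the 18 libraries, computed from log2 CPM of the 500 most variable genes. Colour gives the cultivar label, shape the stage and the number the replicate; E-L 32 libraries lie at the left, and Carlos E-L 35 replicate 3 lies apart from its replicates at 3.90 on component 1.

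From bunch closure to veraison, large falls outnumbered large rises in Noble. With edgeR, 4185 genes rose and 4665 fell among 17657 tested, and at 2-fold or more 1827 rose and 3123 fell. At 16-fold or more the counts were 187 risen and 699 fallen. VIT_14s0128g00200 rose from 79.1 ± 134 to 6286 ± 6064 CPM (SD, n = 3 each), a log2 fold change of 6.31 ± 1.82 (SE, adjusted p = 0.0096). VIT_08s0007g02460 rose from 1.26 ± 0.637 to 97.5 ± 159 CPM, a log2 fold change of 6.29 ± 1.65 (adjusted p = 0.0054). VIT_11s0016g00330 fell from 31.8 ± 4.82 to 0.0570 ± 0.0987 CPM, with a log2 fold change of -9.10 ± 0.58 (adjusted p = 2.5e-07). VIT_05s0020g00420 fell from 11.8 ± 1.41 CPM to 3 counts over the group, a ratio of 300.2 (95% interval 103 to 1456, adjusted p = 1.8e-06). Levels of both risen genes varied with the atypical libraries. VIT_14s0128g00200 stood at 234 CPM in Noble E-L 32 replicate 1 and at 2.89 and 0.89 CPM in replicates 2 and 3, and its log2 fold change was 10.56 without the 3 atypical libraries. Without single libraries it was 11.74 (Noble E-L 32 replicate 1), 5.71 (replicate 2), 5.70 (replicate 3) and 5.14 (Noble E-L 35 replicate 2). VIT_08s0007g02460 stood at 281 CPM in Noble E-L 35 replicate 2 and at 6.71 and 4.96 CPM in replicates 1 and 3. Without that library its log2 fold change was 2.23 and it was not called (adjusted p = 0.13, in a range of 0.00024 to 0.26 over its alternatives), nor was it with limma-voom (0.26). Without the 3 atypical libraries its log2 fold change was 2.7 (adjusted p = 0.00024), and its mean of 5.83 CPM at E-L 35 would miss the minimum of 10 CPM for named genes. The ratio of VIT_05s0020g00420 was 185.5 without them (95% interval 63.5 to 899) and 180.0 without Noble E-L 35 replicate 2 alone (61.6 to 873). All counts of VIT_11s0016g00330 at Noble E-L 35 lay in replicate 3, at 0.17 CPM. It was at least 561-fold lower without that library, and its log2 fold change was -8.43 without replicate 2. At 16-fold or more 306 genes rose and 908 fell without them.

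In Carlos the same step called 9451 genes with edgeR, 4616 higher and 4835 lower at E-L 35. At 2-fold or more 2268 rose and 3056 fell. Changes of 16-fold or more were nearly balanced with all libraries, at 564 genes risen and 586 fallen, but not without the 3 atypical libraries, at 571 risen and 955 fallen. VIT_14s0128g00200 and VIT_12s0028g01180 went from near absence to abundance. The former had 3 counts over the E-L 32 group and 16283 ± 24742 CPM at E-L 35 (SD, n = 3), a ratio of 450960 (95% interval 154310 to 2186800, adjusted p = 0.00011). VIT_12s0028g01180 had 1 count at E-L 32 and 4853 ± 6881 CPM at E-L 35, a ratio of 403260 (95% interval 72376 to 15928000, adjusted p = 5.6e-06). VIT_10s0042g00080 fell from 125 ± 3.45 CPM to 0 counts in every library, at least 2902-fold lower (adjusted p = 1.1e-06). VIT_02s0025g00580 fell from 67.0 ± 4.11 CPM to 0, at least 1553-fold lower (adjusted p = 2.7e-07). The levels of the risen genes came largely from Carlos E-L 35 replicate 3, where VIT_14s0128g00200 stood at 44852 CPM against 2076 and 1920 CPM in the other replicates and VIT_12s0028g01180 at 12799 against 869 and 892 CPM. Without the atypical libraries their ratios were 55343 (95% interval 18938 to 268370) and 73177 (13134 to 2890400). Their counts at E-L 32 lay in replicate 1 alone, and without it VIT_14s0128g00200 was at least 268930-fold and VIT_12s0028g01180 at least 80162-fold higher. Without Carlos E-L 35 replicate 1 VIT_10s0042g00080 was at least 1840-fold and VIT_02s0025g00580 at least 985-fold lower. With limma-voom VIT_14s0128g00200 was not called (adjusted p = 0.058, in a range of 1.4e-09 to 0.058 over its alternatives).

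Noble and Carlos changed largely the same genes in the same direction between E-L 32 and E-L 35. Of 6055 genes called in both cultivars, 5710 (94.3%) moved the same way, 2641 upward and 3069 downward. Independent lists of these sizes would share 1094 risen and 1277 fallen genes. Across genes the fold changes correlated at Pearson r = 0.66, where genes are not independent replicates. Averaged over both labels, 5399 genes rose and 5662 fell, of which 2005 rose and 3184 fell at least 2-fold. VIT_14s0128g00200 was among the named genes in both cultivars.

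From veraison to maturity, averaged over both labels, 2978 genes rose and 3746 fell among 6724 calls (edgeR), and the larger changes were mostly declines. Of genes that changed at least 2-fold, 552 rose and 1960 fell, and at 16-fold or more 10 rose and 239 fell. Without the 3 atypical libraries 3115 of 6384 called genes rose (48.8%), with 570 risen and 1303 fallen at 2-fold or more and 23 risen and 106 fallen at 16-fold or more. This average does not depend on which E-L 38 libraries carry which cultivar name. The steps as labelled do depend on it, and they are given next.

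In libraries labelled Noble, 2696 genes were higher and 3050 lower at E-L 38 than at E-L 35 (edgeR). VIT_09s0018g01360 went from 0 counts in every library to 12.3 ± 2.21 CPM (SD, n = 3), at least 314-fold higher (adjusted p = 0.0024). VIT_19s0093g00190 rose from 22.6 ± 22.9 to 2909 ± 499 CPM, a log2 fold change of 7.01 ± 1.60 (SE, adjusted p = 0.0041). VIT_18s0041g02440 fell from 12.6 ± 2.19 CPM to 0 counts, at least 283-fold lower (adjusted p = 8.4e-07). VIT_06s0004g05400 fell from 48.6 ± 29.6 CPM to 2 counts over the group, a ratio of 1642 (95% interval 455 to 13558, adjusted p = 4e-05). Single libraries moved these values. Without Noble E-L 35 replicate 2 VIT_09s0018g01360 was at least 188-fold higher. At E-L 35 VIT_19s0093g00190 stood at 13.5, 5.70 and 48.6 CPM in replicates 1 to 3, and its log2 fold change was 8.25 without replicate 3. Without replicates 2 and 3 of E-L 38 in turn, VIT_18s0041g02440 was at least 186-fold and 181-fold lower. Both counts of VIT_06s0004g05400 at E-L 38 lay in replicate 3, without which it was at least 699-fold lower, and its ratio was 1077 without replicate 2 (95% interval 298 to 8890). Expected counts were not whole in 9 libraries for VIT_09s0018g01360, in 17 for VIT_19s0093g00190 and in 12 for VIT_06s0004g05400, so their levels depend in part on reads shared with similar genes.

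In libraries labelled Carlos the step from E-L 35 to E-L 38 called 7149 genes, 3308 higher and 3841 lower (edgeR). VIT_04s0008g04060 rose from 0.345 ± 0.301 to 1434 ± 275 CPM (SD, n = 3), a log2 fold change of 11.96 ± 1.25 (SE, adjusted p = 2.1e-05). VIT_06s0004g05330 rose from 0.0621 ± 0.108 to 134 ± 30.4 CPM, a log2 fold change of 11.06 ± 1.06 (adjusted p = 4.4e-06). VIT_09s0002g04850 fell from 91.2 ± 99.2 CPM to 1 count over the group, a ratio of 6473 (95% interval 1162 to 255660, adjusted p = 2.2e-05). VIT_15s0021g00050 fell from 12.05 ± 11.4 CPM to 0 counts, at least 285-fold lower (adjusted p = 9.3e-05). The E-L 35 levels of both fallen genes came largely from replicate 3, at 205.6 against 38.7 and 29.2 CPM for VIT_09s0002g04850 and at 25.2 against 5.11 and 5.83 CPM for VIT_15s0021g00050. Without the atypical libraries the ratio of VIT_09s0002g04850 was 2412 (95% interval 433 to 95255), and VIT_15s0021g00050 was at least 129-fold lower from a mean of 5.47 CPM, which would miss the minimum of 10 CPM for named genes. VIT_06s0004g05330 then had 0 counts at E-L 35 and was at least 2151-fold higher at E-L 38, and its log2 fold change was 10.43 without replicate 1 of E-L 35. The single count of VIT_09s0002g04850 at E-L 38 lay in replicate 2, without which it was at least 1475-fold lower. Its ratio was 4220 without replicate 1 of E-L 38 (95% interval 757 to 166700) and 4302 without replicate 3 (772 to 169900), and the bound of VIT_15s0021g00050 was 186 and 189 without these. Expected counts were not whole in 10 libraries for VIT_04s0008g04060, 14 for VIT_06s0004g05330 and 15 for VIT_15s0021g00050. Fitted to these 6 libraries alone, the comparison called 2746 genes.

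The steps from E-L 35 to E-L 38 did not run alike under the 2 labels. Of 2772 genes called in both, 1304 (47.0%) moved the same way and 1468 moved in opposite directions, and r across genes was 0.01. Independent lists of these sizes would give 1169 in the same and 1158 in opposite directions. Set crosswise, with E-L 38 libraries labelled Carlos against Noble at E-L 35 and those labelled Noble against Carlos at E-L 35, 1601 genes were called in both steps. Of these 1551 (96.9%) moved the same way, and r was 0.54. The crosswise comparison was chosen after the data were examined.

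At bunch closure, with cultivars named as labelled, Noble and Carlos differed in 4852 genes, 2444 higher in Noble and 2408 higher in Carlos (edgeR). At 16-fold or more, 385 genes were higher in libraries labelled Noble and 95 in those labelled Carlos. VIT_04s0008g04060 stood at 203 ± 46.4 CPM in Noble (SD, n = 3) and at 0 counts in Carlos, at least 5620-fold higher (adjusted p = 4.1e-05). VIT_12s0059g02350 stood at 95.3 ± 6.96 CPM in Noble and at 0 in Carlos, at least 2640-fold higher (adjusted p = 7e-05). VIT_06s0061g00970 was at 0 counts in Noble and 21.7 ± 0.538 CPM in Carlos, at least 553-fold lower in Noble (adjusted p = 0.00055). VIT_07s0005g05180 stood at 0.765 ± 0.380 CPM in Noble and 99.6 ± 7.47 CPM in Carlos, a log2 fold change of -6.98 ± 0.84 (SE, adjusted p = 3.1e-05). Without Carlos replicate 1 the bounds of VIT_04s0008g04060 and VIT_12s0059g02350 were 3352 and 1574, and without Noble replicate 3 that of VIT_06s0061g00970 was 342. A fit to these 6 libraries alone called 9298 genes, and upper-quartile scaling moved the share of calls that were higher in Noble from 50.4% to 60.5%. On the first component Carlos E-L 32 libraries lay at -112.0 to -112.9, farther from E-L 35 than Noble replicates 2 and 3, at -79.1 and -82.9. The design does not separate a difference in ripeness at this stage from a difference between cultivars.

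At veraison 3356 genes differed between the labels, 1722 higher in Noble and 1634 higher in Carlos (edgeR). VIT_04s0008g04060 again led on the Noble side, at 1179 ± 256 CPM against 0.345 ± 0.301 CPM (SD, n = 3), a log2 fold change of 11.68 ± 1.24 (SE, adjusted p = 5.6e-05). VIT_18s0041g02440 stood at 12.6 ± 2.19 CPM in Noble and at 0 counts in Carlos, at least 292-fold higher (adjusted p = 2.8e-06). VIT_19s0015g02680 stood at 11.3 ± 13.0 CPM in Noble and 938 ± 788 CPM in Carlos, a log2 fold change of -6.38 ± 1.55. VIT_19s0093g00190 stood at 22.6 ± 22.9 and 1832 ± 1536 CPM, a log2 fold change of -6.34 ± 1.55, and both had an adjusted p of 0.011. Expected counts of both genes were not whole in 17 libraries, and Carlos replicate 3 lay far below its replicates, at 28.3 against 1389 and 1397 CPM for VIT_19s0015g02680 and at 57.6 against 2710 and 2727 CPM for VIT_19s0093g00190. Without Noble E-L 35 replicate 3 the log2 fold changes were -7.93 for VIT_19s0015g02680 and -7.58 for VIT_19s0093g00190, and without Carlos replicate 1 the bound of VIT_18s0041g02440 was 185. The calls of VIT_19s0015g02680 and VIT_19s0093g00190 ended without Noble E-L 35 replicate 1 (adjusted p = 0.056 for VIT_19s0015g02680 and 0.057 for VIT_19s0093g00190) and in a fit to these 6 libraries alone (0.11 and 0.10), with lowest values over all alternatives of 5.4e-06 and 1.9e-06. The count of called genes depended on single libraries: it was 449 in that smaller fit, 1869 without Noble replicate 1, 2166 without Noble replicate 3 and 5841 without the 3 atypical libraries of E-L 32 and E-L 35.

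**Figure D2:**
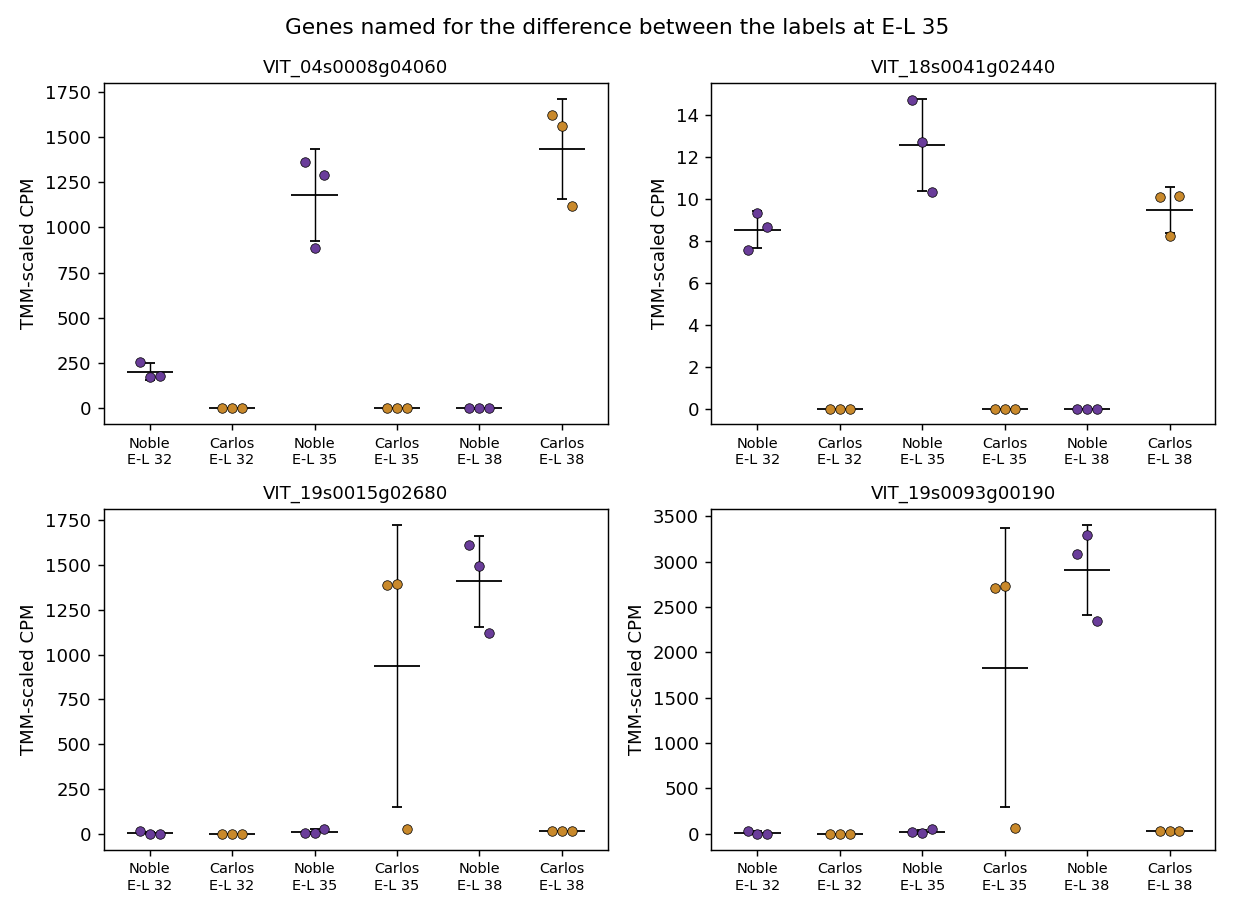
CPM after TMM scaling (vertical axis, linear) of the 4 genes named for the difference between labels at E-L 35, by cultivar label and stage. Points are libraries, horizontal lines group means and bars the SD of 3 libraries; VIT_18s0041g02440 is at 0 in Carlos at E-L 32 and E-L 35 and in Noble-labelled libraries at E-L 38.

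At maturity 4130 genes differed between the labels, 2013 higher in libraries labelled Noble and 2117 higher in those labelled Carlos (edgeR). VIT_09s0002g04850 stood at 14.3 ± 4.57 CPM under the Noble label (SD, n = 3) and at 1 count over the Carlos group, a ratio of 1012 (95% interval 182 to 39972, adjusted p = 0.00035). VIT_19s0015g00540 stood at 33.0 ± 0.559 against 0.0688 ± 0.0837 CPM, a log2 fold change of 8.78 ± 2.19 (SE, adjusted p = 0.0097). VIT_06s0004g05400 was at 2 counts over the Noble group and at 232 ± 96.1 CPM under the Carlos label, a ratio of 7826 in favour of Carlos (95% interval 2166 to 64618, adjusted p = 1.2e-05). VIT_06s0004g05330 stood at 0.0547 ± 0.0947 against 134 ± 30.4 CPM, a log2 fold change of -11.03 ± 1.06 (adjusted p = 8.7e-06). Without Carlos replicate 2 VIT_09s0002g04850 was at least 231-fold higher under the Noble label, and its ratio was 660 without Carlos replicate 1 (95% interval 118 to 26063) and 673 without replicate 3 (121 to 26564). Without Carlos replicate 1 VIT_19s0015g00540 had 1 count left in that group, a ratio of 1529 (274 to 60396). Without Noble replicate 3 VIT_06s0004g05400 was at least 3332-fold and VIT_06s0004g05330 at least 1928-fold lower under the Noble label, and without Noble replicate 2 the ratio of VIT_06s0004g05400 was 5131 (1420 to 42368). With limma-voom VIT_09s0002g04850 (adjusted p = 0.086, in a range of 5.4e-10 to 0.086) and VIT_19s0015g00540 (0.32, in a range of 9.7e-09 to 0.32) were not called. Without the 3 atypical libraries, none of them from E-L 38, the fit called 6671 genes.

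Differences between the labels mostly kept their direction from E-L 32 to E-L 35 among genes called at both, and mostly ran opposite at E-L 38. Of 1384 genes called at both E-L 32 and E-L 35, 1039 (75.1%) had 1 sign and 345 had opposite signs, against 461 of each for independent lists, and r across genes was 0.20. Of 1672 genes called at both E-L 32 and E-L 38, 1265 had opposite signs and 407 had 1 sign, against 568 and 567 for independent lists, with r = -0.13. Of 1815 genes called at both E-L 35 and E-L 38, 54 (2.98%) had 1 sign and 1761 had opposite signs, against 392 and 393 for independent lists. Across genes the differences at E-L 35 and E-L 38 correlated at r = -0.55. At least a 4-fold difference of 1 sign at both E-L 32 and E-L 35 was found in 184 genes, of which 125 were called at E-L 38. Of those, 124 had the opposite sign there and 1, VIT_05s0020g01690, the same. The 96 genes of the set that were higher in Noble had a median log2 difference of 3.85 at E-L 32, 3.51 at E-L 35 and -3.27 at E-L 38, and the 88 that were higher in Carlos had medians of -3.60, -3.86 and 3.45. VIT_18s0041g02440 stood at 8.53 ± 0.890 and 12.6 ± 2.19 CPM in Noble at E-L 32 and E-L 35 and at 0 counts in all 3 Noble-labelled libraries of E-L 38, where those labelled Carlos held 9.49 ± 1.09 CPM after 0 counts at both earlier stages. These comparisons of stages were chosen after the data were examined.

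**Figure D3:**
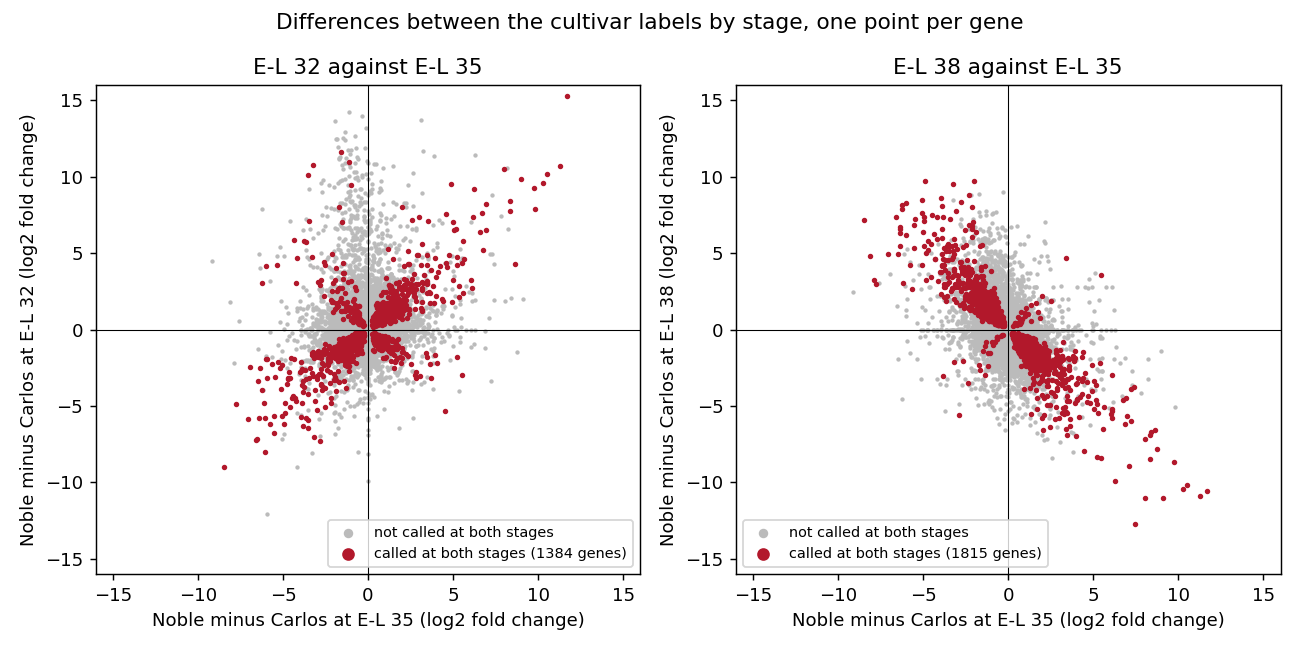
Noble minus Carlos difference of each gene (log2 fold change, edgeR) at E-L 32 (left, vertical axis) and at E-L 38 (right, vertical axis) against that at E-L 35 (horizontal axes). Red points are genes called at both stages of a panel, of which 1039 of 1384 share their sign at the left and 54 of 1815 at the right.

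The step from E-L 32 to E-L 35 differed between the cultivars in 3108 genes by the edgeR interaction test, 1534 with a more positive change in Noble and 1574 with a more positive change in Carlos. Upper-quartile scaling moved the share with a more positive change in Noble from 49.4% to 39.7% (1261 of 3179). VIT_04s0008g04160 went from 1.34 ± 0.397 to 0.775 ± 0.254 CPM in Noble and from 53.4 ± 0.485 to 0.0286 ± 0.0251 CPM in Carlos (SD, n = 3, adjusted p = 1.6e-06). VIT_10s0042g00080 went from 7.57 ± 0.722 to 0.214 ± 0.370 CPM in Noble and from 125 ± 3.45 CPM to 0 in Carlos (adjusted p = 0.009). VIT_05s0077g01930 went from 993 ± 116 to 169 ± 81.1 CPM in Noble and from 0.0628 ± 0.0773 to 656 ± 988 CPM in Carlos, a log2 difference of -15.62 ± 1.99 (SE, adjusted p = 0.00013, expected counts not whole in 8 libraries). VIT_12s0059g02350 went from 95.3 ± 6.96 to 267 ± 230 CPM in Noble and from 0 to 569 ± 661 CPM in Carlos (adjusted p = 0.00023). In Carlos E-L 35 replicate 3 VIT_05s0077g01930 stood at 1797 CPM, against 81.7 and 90.9 CPM in replicates 1 and 2, and VIT_12s0059g02350 at 1332 CPM, against 188 and 186 CPM. The log2 difference of VIT_05s0077g01930 was -13.23 without the 3 atypical libraries, -12.69 without Carlos E-L 35 replicate 3 and -17.23 without Carlos E-L 32 replicate 1. Calls ended for VIT_10s0042g00080 without Noble E-L 35 replicate 3 (adjusted p = 1, in a range of 0.0018 to 1), and with limma-voom for VIT_05s0077g01930 (0.06, from 2e-19) and VIT_12s0059g02350 (0.051, from 2.7e-17). The count was 4770 without Carlos E-L 35 replicate 3 and 5252 without the 3 atypical libraries.

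From E-L 35 to E-L 38 the step as labelled differed between Noble and Carlos in 5890 genes, 2976 with a more positive change under the Noble label and 2914 under the Carlos label (edgeR). VIT_06s0004g01300 went from 0.180 ± 0.178 to 5.34 ± 0.134 CPM under the Noble label and from 13.4 ± 3.26 to 0.0140 ± 0.0242 CPM under the Carlos label (SD, n = 3, adjusted p = 4.2e-08). VIT_19s0015g02680 went from 11.3 ± 13.0 to 1409 ± 256 CPM and from 938 ± 788 to 13.6 ± 0.785 CPM, a log2 difference of 13.07 ± 2.21 (SE, adjusted p = 0.00039). VIT_04s0008g04060 went from 1179 ± 256 to 0.929 ± 1.61 CPM and from 0.345 ± 0.301 to 1434 ± 275 CPM, a log2 difference of -22.21 ± 1.71 (adjusted p = 1.1e-06). VIT_18s0041g02440 went from 12.6 ± 2.19 CPM to 0 and from 0 to 9.49 ± 1.09 CPM (adjusted p = 6e-08). The log2 difference of VIT_19s0015g02680 was 14.63 without Noble E-L 35 replicate 3 and 13.67 without Carlos E-L 35 replicate 3. That of VIT_04s0008g04060 was -21.62 without Carlos E-L 35 replicate 3 and -21.60 without Noble-labelled E-L 38 replicate 2, and its counts in Noble-labelled E-L 38 libraries lay in replicate 3 alone, at 2.79 CPM. With the cultivar labels of E-L 38 exchanged, 485 genes were called.

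In Carlos E-L 35 replicate 3, 238 genes stood at least 8-fold above both other replicates and together took 26.1% of its counts, against 1.32% and 1.26% in replicates 1 and 2. Another 253 genes stood at least 8-fold below both other replicates. The same 238 genes took 7.22% of the counts of Noble E-L 35 replicate 2, and 1.41% and 1.77% in Noble replicates 1 and 3. Most of that share came from VIT_07s0005g03420, VIT_07s0005g03410 and VIT_14s0128g00200, the 3 genes of the set with the highest counts in that library, which took 5.86% there. The other genes of the set took 1.36%, against 0.386% and 0.580%. In Carlos replicate 3 the same 3 genes took 21.2% of the counts, against 1.04% and 0.998% in replicates 1 and 2. There the other genes of the set took 4.85%, against 0.273% and 0.265%. The median log2 CPM of the set was 0.67 in Noble replicate 2, -0.50 and 0.47 in Noble replicates 1 and 3, and 2.85 in Carlos replicate 3. At E-L 32 this median was already 2.60 to 2.72 in Noble libraries and 0.65 to 0.81 in Carlos libraries. Without its 3 top genes the set took 1.20% to 1.34% of the counts in Noble E-L 32 libraries and 0.964% to 0.976% in Carlos E-L 32 libraries. High levels of most of the set are therefore not particular to the atypical E-L 35 libraries. In Noble replicate 2, 83 of the 238 genes (34.9%) stood over 2-fold above both other replicates. VIT_07s0005g03410, singled out after its values were seen, stood at 94847 CPM in Carlos replicate 3 and 21236 CPM in Noble replicate 2, and between 2699 and 3629 CPM in the other E-L 35 libraries. The set was chosen on Carlos replicate 3, so its share there is high by construction.

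**Figure D4:**
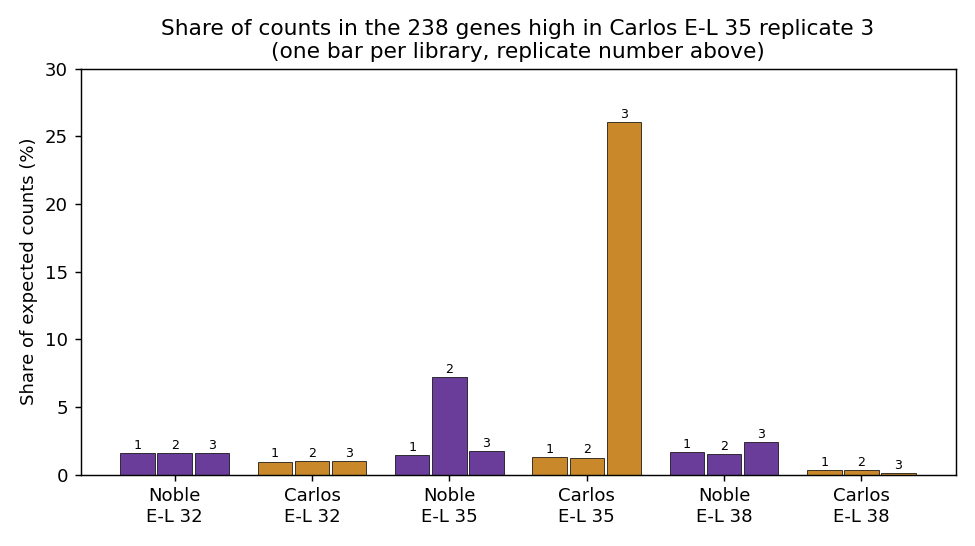
Share of expected counts (%, vertical axis) held by the 238 genes that stood at least 8-fold higher in Carlos E-L 35 replicate 3 than in both its replicates, with 1 bar per library and the replicate number above it. The share is 26.1% in that library, 7.22% in Noble E-L 35 replicate 2 and at most 2.40% in any other. In that Carlos library 3 genes of the set hold 21.2% of all counts.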

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

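Of the tests in this part, the share of opposite signs at E-L 38, the tests of other berry parts and of mixed stages, the spread of relative levels in Noble E-L 32 replicate 1 and the level set beside its dilution were chosen after the result was seen, as were the steps averaged over both labels and the exchange of labels.

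The response to each stage step differed between the cultivar labels by the edgeR interaction test, in 3108 genes from E-L 32 to E-L 35 and in 5890 genes from E-L 35 to E-L 38. Named genes that differed in the first of these steps were VIT_04s0008g04160 (adjusted p = 1.6e-06), VIT_10s0042g00080 (0.009), VIT_05s0077g01930 (0.00013) and VIT_12s0059g02350 (0.00023). The last 3 each lost the call under 1 alternative, VIT_10s0042g00080 without Noble E-L 35 replicate 3 (adjusted p = 1, in a range of 0.0018 to 1), and VIT_05s0077g01930 (0.06, from 2e-19) and VIT_12s0059g02350 (0.051, from 2.7e-17) with limma-voom. In the later step they were VIT_06s0004g01300 (adjusted p = 4.2e-08), VIT_19s0015g02680 (0.00039), VIT_04s0008g04060 (1.1e-06) and VIT_18s0041g02440 (6e-08).

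Most genes called between the cultivar labels at E-L 38 and at an earlier stage had opposite signs, 1761 of 1815 for E-L 35 and 1265 of 1672 for E-L 32. Among the 125 genes called at E-L 38 that differed at least 4-fold with 1 sign at E-L 32 and E-L 35, 124 were opposite. A candidate explanation is that the names Noble and Carlos were exchanged between E-L 38 and the earlier stages. Exchanging the E-L 38 labels lowered the interaction from 5890 to 485 genes. That drop follows largely from the opposite signs and is no separate support. The atypical E-L 35 libraries are argued against as the source, because the correlation across genes of the differences at E-L 35 and E-L 38 was -0.43 without them and -0.55 with them. These files do not tell at which stage an exchange would have taken place. Regulation that turns round between the cultivars at maturity was not tested and stays open.

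Of the 238 genes high in Carlos E-L 35 replicate 3, 70.2% were highest in replicate 2 among the Noble E-L 35 libraries, by less: the median log2 excess was 1.04 there and 3.89 in the Carlos library, and the excesses correlated at 0.31 across genes. Another part of the berry may be the source, but any shared cause gives this and no marker list was tested, so it stays open, as does a difference in ripeness within a stage. In Carlos replicate 3, a mix of E-L 32 and E-L 35 berries of the Carlos label is argued against for 139 of the 238 genes (58.4%). These stood over 2-fold above every Carlos E-L 32 library. For the rest of the set it stays open. Berries of the Noble label at E-L 32 were not tested as a source in that library. Nor was a mix of stages tested for Noble replicate 2. There the set without its 3 top genes took 1.36% of the counts, against 1.20% to 1.34% in Noble E-L 32 libraries. A few genes taking most of the counts is argued against as a source of the excess in the other genes, by the direction of its effect. The 10 most abundant genes took 29.6% of the counts in Carlos replicate 3 and 5.84% and 5.76% in replicates 1 and 2. That lowers the other genes of replicate 3. Given these shares, leaving the 10 genes out of plain totals could only raise the median log2 excess of the set, here from 2.79 to 3.23. It therefore adds no separate evidence. Another 253 genes stood at least 8-fold lower in Carlos replicate 3 than in both other replicates, and no cause was tested for them.

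Noble E-L 32 replicate 1 lay nearer the E-L 35 libraries than its replicates did. In 47 genes near absent in replicates 2 and 3 it stood at a median of 9.16% of the Noble E-L 35 mean, and the upper quartile of this relative level was 1.55 times the lower. Genes near absent at Noble E-L 35, of which there were 5, stood at a median of 0.841 of their level in replicates 2 and 3. Dilution by the median share would leave 0.908, above the quartiles of 0.834 and 0.905 of these 5 genes, so they do not settle whether dilution alone is enough. A fixed share of Noble E-L 35 material could give the even relative levels of the 47 genes, and so might berries that had begun to ripen. The design does not separate these. The 47 genes all had a mean of at least 50 CPM at Noble E-L 35, a mean that atypical replicate 2 enters. Below that minimum, VIT_19s0093g00190 stood at 31.2 CPM in Noble E-L 32 replicate 1 and at a mean of 22.6 CPM at Noble E-L 35. VIT_19s0015g02680 stood at 13.4 and 11.3 CPM. A share of 9.16% of Noble E-L 35 material would not give these levels, and other genes below the minimum were not counted. In Carlos E-L 35 replicates 1 and 2 VIT_19s0093g00190 stood at 2710 and 2727 CPM and VIT_19s0015g02680 at 1389 and 1397 CPM. Both were also high in Noble-labelled E-L 38 libraries, at means of 2909 and 1409 CPM. Material of these groups was not tested as a source, and expected counts of both genes were not whole in 17 libraries.

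Other splits of the libraries into groups of the same sizes were counted for every comparison. For comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For E-L 35 against E-L 32, 1 of the 10 splits, the real one, gave as many genes as the 8850 in Noble and the 9451 in Carlos, and the highest other split gave 0 in each. For E-L 38 against E-L 35, 1 of 10 gave as many as the 5746 under the Noble label (highest other 15) and as the 7149 under the Carlos label (highest other 230). Between the labels, 1 of 10 gave as many as the 4852 at E-L 32 (highest other 0), the 3356 at E-L 35 (highest other 839) and the 4130 at E-L 38 (highest other 1). For contrasts of 4 groups, 100 of 200 splits were drawn and the real one alone, 1 of 100, gave as many genes. For the steps over both labels this share is under 0.05. The real and highest other counts were 11061 and 6633 for E-L 35 against E-L 32 and 6724 and 3560 for E-L 38 against E-L 35. The share speaks only to how these libraries were assigned to stages. Since replicates may be technical, it does not exclude chance differences between the berries sampled. For the interactions the counts were 3108 and 2695 from E-L 32 to E-L 35 and 5890 and 3118 from E-L 35 to E-L 38, but those splits also break up the cultivar difference at each stage, so they do not test the interaction by itself.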

How the results depend on the processing

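Leaving out the 3 atypical libraries together, exchanging the E-L 38 labels and averaging steps over both labels were chosen after the data were examined. Of 209 alternative values of counts and component shares, 183 lay within 1.5 times the main value and 26 moved. No named gene changed direction in 580 alternative values, 568 kept the call and 12 lost it, in 9 of 36 results. The named genes were chosen for extreme fold changes, so this says little about other calls. The exchange of E-L 38 labels is not among these 580 values. DESeq2 gave no adjusted p for 8 of the 36 results, so 28 were compared. RLE and upper-quartile scaling, both filters, DESeq2, limma-voom and the replicate block kept every count of calls within 1.5 times. Upper-quartile scaling shifted the median log2 change of all genes to -0.108 for Noble E-L 35 against E-L 32 and to -0.124 for the interaction from E-L 32 to E-L 35, against -0.015 and -0.041 with TMM, and lowered the share of calls that were higher from 47.3% to 40.1% and from 49.4% to 39.7%. Tests of the planned gene lists were not run, since no identifier could be matched in the 1 reference table searched. At the real depths and with 3 replicates the simulated comparisons, in which few genes were changed, recovered few of the smaller changes. Neither depth nor replicate number was varied.

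Requiring a 2-fold change lowered the counts by construction, to 4950 for Noble E-L 35 against E-L 32, 2747 for Noble E-L 38 against E-L 35, 5324 and 3662 for these steps in Carlos, 2345, 1499 and 2124 between the labels at E-L 32, E-L 35 and E-L 38, 1891 and 3898 for the interactions, and 5189 and 2512 for the steps over both labels. Calls of the same direction in both cultivars fell from 5710 to 3207 for the earlier step and from 1304 to 609 for the later one. Fits to the compared libraries alone gave 2746 genes for Carlos E-L 38 against E-L 35, 9298 between the labels at E-L 32 and 449 at E-L 35, and the cause of these moves in both directions was not tested. Without the 3 atypical libraries 5841 genes were called between the labels at E-L 35, 6671 at E-L 38 and 5252 in the interaction from E-L 32 to E-L 35. Exchanged labels at E-L 38 gave 3787 genes for Carlos E-L 38 against E-L 35 and 485 for the later interaction. Leaving out each replicate in turn gave 1869 to 4944 genes between the labels at E-L 35 and 2105 to 4770 in the interaction from E-L 32 to E-L 35. With all tested genes the first component held 61.3% and the second 11.2% of the variance. Where no construction is named, the cause was not tested.

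Little sign of pairing by replicate number was seen. Deviations of same-numbered libraries correlated between -0.229 and 0.31, above 0.1 in 5 of 45 pairs, and 5 of 18 libraries correlated best with their own number. These correlations cannot show whether a number stands for a shared plant, day or batch. With the replicate number as a block, 8517 genes were called for Noble E-L 35 against E-L 32 and 3014 between the labels at E-L 35.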

Other observations

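The tests in this part on identifier order were planned before their result was seen, and the count of genes near absent in 1 cultivar was chosen after the data were examined.

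At bunch closure 82 genes stood at a mean of at least 5 CPM in Noble with at most 3 counts in any Carlos library, and 1 gene, VIT_06s0061g00970, did so in Carlos and not in Noble. Of the 82 genes, 64 reached at least 1 CPM in Carlos at E-L 35, where their median was 28.8 CPM against 14.9 CPM in Noble. Noble E-L 32 replicate 1 and Carlos E-L 35 replicate 3 enter these means. Over Noble replicates 2 and 3 alone 69 of the 82 stayed at 5 CPM or more, and 43 of these 69 reached 1 CPM over Carlos E-L 35 replicates 1 and 2, with a median over the 69 genes of 5.64 CPM there and 7.23 CPM over Noble E-L 35 replicates 1 and 3. VIT_12s0059g02350 is an example, at 0 counts in Carlos at E-L 32 and at 188, 186 and 1332 CPM in the Carlos libraries of E-L 35. At E-L 38, 48 of the 82 genes reached 1 CPM under the Noble label and 48 under the Carlos label, with medians of 11.4 and 4.93 CPM. By the same measure 3 genes were near absent in Carlos alone at E-L 35, all 3 at 1 CPM or more in E-L 38 libraries labelled Carlos and 0 of them in those labelled Noble. No test was made of these counts, and they do not separate cultivar from ripeness within a stage.

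Genes that differed between the cultivar labels tended to lie beside each other in identifier order. Among the 184 genes with at least a 4-fold difference of 1 sign at E-L 32 and E-L 35, 14 pairs were neighbours among the tested VIT_ identifiers and shared their sign. Random sets of 184 genes gave a mean of 0.955 such pairs and at most 6 in 10000 draws (permutation test, one-sided p = 0.0001, the smallest these draws can give). The longest run held 5 genes, from VIT_12s0134g00280 to VIT_12s0134g00380. Clusters of related neighbouring genes that differ between the cultivars may account for this. Reads shared between similar neighbours may add to it, since 10 of the 14 pairs held a gene with expected counts that were not whole, against 17.0% of the 17632 adjacent pairs of tested VIT_ genes. Of the 184 genes 33.2% had such counts, against 11.8% of all tested VIT_ genes. Part of the excess among the pairs therefore belongs to the set as a whole and not to neighbours.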
